A study of Mus musculus with 12 samples.

How the data were processed

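RNA of immortalized mouse embryonic fibroblasts (MEF, ICR background) was measured on 12 arrays, 3 in each of 4 groups. The cells had been infected for 2 h with an adenovirus that expressed either a scramble RNA or a short hairpin RNA against HSF1, the main transcription factor of the heat shock response. They were then kept in normal medium for 70 h. In each of the 2 cell populations, cells were left at 37°C or were heated at 42°C for 1 h and returned to 37°C for 6 h. Total RNA was extracted with a column kit, and 200 ng per sample was turned into biotin-labelled cDNA, per the labels' protocols. The array was the Affymetrix GeneChip Mouse Gene 1.0 ST, a 1-colour array whose probes lie along the exons of each transcript. The replicates are separate samples by their titles. The labels do not say whether they came from separate cultures, so the p-values measure the spread between these samples, which can be technical.

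The deposited table holds log2 expression values made by the authors, 1 value per probe set and array, for 35557 probe sets. The submitters' processing notes name Partek 6.5, and the normalization method and background correction are not given in the sources used here. The log base is not stated either. It was read from the values, which run from 1.09 to 14.67, a range that fits log2 intensities of a scanner. All fold changes below rest on that reading. Array medians lay between 6.94 and 7.06, which was read as normalized between arrays, so the values were used as deposited. The medians of all heated arrays (7.00 to 7.06) lay above those of all unheated ones (6.94 to 6.99). No 2 arrays held identical values. Detection calls, scan dates and hybridization batches were not used here, so a batch that followed the groups cannot be separated from them, and no probe set was called absent. The number of arrays limits the precision, and there is no read depth.

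Genes were named from the platform annotation of the probe sets. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 were not named here. Only probe sets with 1 symbol name a gene, and these cover 19938 genes. Of the 1-symbol probe sets, 21698 had their gene ID in a RefSeq gene table of assembly GRCm38.p6, 0 of them under another symbol. That table was used for names and for which genes lie near each other. No coordinates are given, because the build behind the array annotation is not given in the sources used here. For the 999 genes with more than 1 such probe set, the one with the highest mean over all arrays stands for the gene. The probe sets of Hsf1 were not analysed here, because none carries that symbol alone in the annotation. The knockdown was therefore not checked through its target, and the groups rest on the labels alone. Hspa1b was measured only by a probe set shared with its near-identical copy Hspa1a and is not named. Part of the Hspa1a signal can come from Hspa1b for the same reason.

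All 12 arrays entered 1 linear model per probe set with a term for each group, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 8 residual degrees of freedom). The 5 contrasts were heat shock in scramble cells, HSF1 knockdown in unheated cells, HSF1 knockdown in heat-shocked cells, heat shock in knockdown cells, and the interaction, which is the heat response of knockdown cells minus that of scramble cells. P-values were two-sided and adjusted by Benjamini-Hochberg within each contrast over all probe sets, with no filter, and the threshold was an adjusted p of 0.05. Every adjusted p of a gene given below is from this fit unless another fit is named beside it. Errors of log2 fold changes are standard errors of the fit, with n = 3 arrays per group.

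Before the data were examined, 31 gene lists were written down, covering chaperones, stress responses, cell cycle, matrix, metabolism and markers of other cell types. The design, the processing alternatives and the rule for naming genes were fixed then too. Lists with at least 5 measured genes were tested with limma's camera on 1 probe set per gene, with a preset inter-gene correlation of 0.01. Its p-values were adjusted over 150 tests (30 lists in 5 contrasts). The list of mitochondrially encoded transcripts had too few measured members and was not tested. Of the 34 list calls, 10 held with a correlation estimated from the data. For each list the number of members past the threshold is given over all probe sets and adjusted over the list alone. The rule for naming genes took, per contrast, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose replicates did not overlap (without that condition for the interaction). It added up to 4 members per list with the largest change past the threshold, and 6 measured chaperone genes in every contrast (Hspa1a, Hsp90aa1, Hspb1, Hsph1, Dnajb1 and Bag3).

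The fit was tested on simulated data for the 35557 probe sets, drawn around the means of the unheated scramble arrays with the fitted spread of each probe set. For heat shock in scramble cells, 55.2% of probe sets changed by 0.5 on the log2 scale were recovered, 83.6% of those changed by 1 and 98.5% of those changed by 2. For the interaction these shares were 29.9%, 74.6% and 97%, so small differences between the heat responses were often missed in these simulations. Each simulation changed 67 probe sets by 0.5, 67 by 1 and 66 by 2, fewer than were called in any contrast of the data. The adjusted threshold depends on how many probe sets change, so these shares do not give the shares recovered in the data. Of the simulated calls 7.59% were false for the interaction, above the 5% aimed at, and 4.82% to 5.95% for the other contrasts. In simulations of the list test over 19938 genes, 20 of 20 lists shifted by 0.3 were called, as was 1 of 580 tests of unshifted lists. The noise of each gene was drawn independently there. These values therefore do not show how often lists of correlated genes are called falsely.

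The alternatives were a filter that removed the 30 percent of probe sets with the lowest means, 1 probe set per named gene only, quantile normalization, a common median for all arrays, a fit of only the arrays compared, eBayes with trend and robust options, array weights, the replicate number as a block, an added threshold of a 2-fold change, the mean of all probe sets of a gene, the estimated correlation, and leaving out each array in turn.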

Results

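Transcript levels were measured in immortalized mouse embryonic fibroblasts with or without knockdown of HSF1, the transcription factor that drives heat shock gene expression, and with or without heat shock. Each of the 4 groups had 3 arrays. Scramble and knockdown cells were either unheated or heated at 42°C for 1 h and collected after 6 h of recovery at 37°C. The title of the series names its purpose, the identification of genes regulated by HSF1 in both conditions. Arrays of 1 group correlated over all probe sets with r between 0.992 and 0.995, and arrays of heated and unheated scramble cells with r between 0.983 and 0.988. Unheated knockdown and scramble arrays had r between 0.992 and 0.994, inside the range of replicates, and heated ones r between 0.988 and 0.990. Heated and unheated knockdown arrays had r between 0.981 and 0.983. The level of Hsf1 itself was not analysed here, so the knockdown groups rest on their labels.

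Heat shock in scramble cells, which asks what heat does when HSF1 is present, raised cytosolic chaperone genes. Hspa1a (probe set 10450369), which encodes the inducible HSP70, had the largest rise of any named gene and rose 42.2-fold (log2 change 5.40 ± 0.11, SE, n = 3 per group, adjusted p = 3.23e-09, limma), from a mean log2 level of 8.08 to 13.48. This value can include its near-identical copy Hspa1b. Hsph1, an HSP110 that acts as exchange factor of HSP70, rose 9.03-fold. The HSP40 co-chaperones Dnaja4 and Dnajb1 rose 7.9-fold and 6.29-fold, and the small heat shock protein gene Hspb1 rose 6.08-fold. The co-chaperone Bag3 rose 3.99-fold and Hsp90aa1, the inducible HSP90, 2.13-fold. In the list of HSP70, HSP110, HSP40 and small HSP chaperones, 16 of 29 measured genes were higher and 0 lower (18 and 1 adjusted over the list alone), with a mean log2 change of 0.99 (camera adjusted p = 2.27e-12). Of 17 HSP90 and co-chaperone genes, 9 were higher, Fkbp4 and Ahsa1 among them (log2 changes 0.59 ± 0.06 and 0.53 ± 0.06), and 1 was lower, the same counts adjusted over the list alone. Their mean log2 change was 0.23 (camera adjusted p = 0.00295), and this list's call was lost with an estimated correlation (adjusted p = 0.146).

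Immediate-early genes, which are transcribed within minutes of many stimuli, were higher 6 h after the heat than in unheated cells. Of 26 measured members, 24 were higher and 0 lower (25 and 0 adjusted over the list alone), with a mean log2 change of 1.16 (camera adjusted p = 2.15e-22). Fosb, a partner of Jun in the AP-1 transcription factor, rose 10.05-fold, and the MAP kinase phosphatase genes Dusp2, Dusp5 and Dusp1 rose 5.28-fold, 4.32-fold and 3.78-fold. Outside the lists, large rises were those of the cornified envelope gene Sprr1a (3.17 ± 0.10), the protease inhibitor gene Serpinb2 (3.07 ± 0.13) and the semaphorin gene Sema6a (2.77 ± 0.23). The keratin-associated gene Krtap4-16 also rose, from a mean level of 4.93 to 8.98, but its unheated level lay below the lower quartile of every array (5.57 to 5.63), so no fold is given. Of 20 mitochondrial chaperone and protease genes 4 were higher and 6 lower (6 and 7 adjusted over the list alone), and among the 4 the chaperonin pair Hspd1 and Hspe1 rose 1.95-fold and 2.00-fold. The list had no call (adjusted p = 0.936), with a mean of 0.03, a median of -0.03 and a test direction of down.

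Interferon-stimulated genes fell with heat. In this list of antiviral genes, 22 of 26 measured members were lower and 0 higher (23 and 0 adjusted over the list alone), with a mean log2 change of -0.74 (camera adjusted p = 5.20e-10). The call was lost with an estimated correlation (adjusted p = 0.621). Ifit3, Ifit1 and Rtp4 changed by -1.55 ± 0.14, -1.49 ± 0.09 and -1.49 ± 0.16 on the log2 scale, and Dhx58 by -1.16 ± 0.14. Samd9l (-1.39 ± 0.11) and Tlr1 (-1.38 ± 0.12), both genes of innate immunity, were also among the 10 largest falls. BC023105 fell from a mean level of 6.64 to 4.65, below the lower quartile of every array, so no size of its fall is given.

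Several smaller list shifts with heat in scramble cells passed the preset test and not the one with an estimated correlation. Nucleolar ribosome biogenesis genes were higher, with 15 of 24 up and 0 down (also 15 and 0 adjusted over the list alone), Nolc1 and Rrs1 leading at 0.62 ± 0.05 and 0.61 ± 0.06 (mean 0.22, adjusted p = 3.14e-05, and adjusted p = 0.433 with an estimated correlation). G2 and mitosis genes were lower, 14 of 24 down and 2 up (16 and 3 adjusted over the list alone), Cenpe at -0.57 ± 0.06 and Mki67 at -0.52 ± 0.07 (mean -0.18, adjusted p = 0.00118, and adjusted p = 0.603 with an estimated correlation). Of 18 cholesterol synthesis and uptake genes, 7 were lower and 0 higher (11 and 0 adjusted over the list alone), with Idi1 at -0.56 ± 0.11 and Msmo1 at -0.53 ± 0.08 (mean -0.26, adjusted p = 0.000969, and adjusted p = 0.735 with an estimated correlation). Of 16 circadian clock genes 5 were higher and 1 lower (the same adjusted over the list alone). Bhlhe41 rose by 1.29 ± 0.11 and Nr1d1 by 1.16 ± 0.08 (list mean 0.25, adjusted p = 0.0322, and adjusted p = 0.626 with an estimated correlation). The clock list's call also ended with dim probe sets left out (adjusted p = 0.0626), with only the arrays compared (adjusted p = 0.0519), without the unheated scramble replicate 3 (mean 0.23, adjusted p = 0.0764) and without the heated scramble replicate 1 (mean 0.23, adjusted p = 0.0881).

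Across all 35557 probe sets, 4335 were higher and 4624 lower with heat in scramble cells, 383 and 75 of them by at least 2-fold. Among the 19938 genes 2798 were higher and 3383 lower past the threshold. The replicates of both groups did not overlap for 37.4% of probe sets, against 10% by chance. With each array shifted to a common median the split was 3451 higher and 5548 lower, a share of higher calls of 38.3% against 48.4%.

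**Figure D1:**
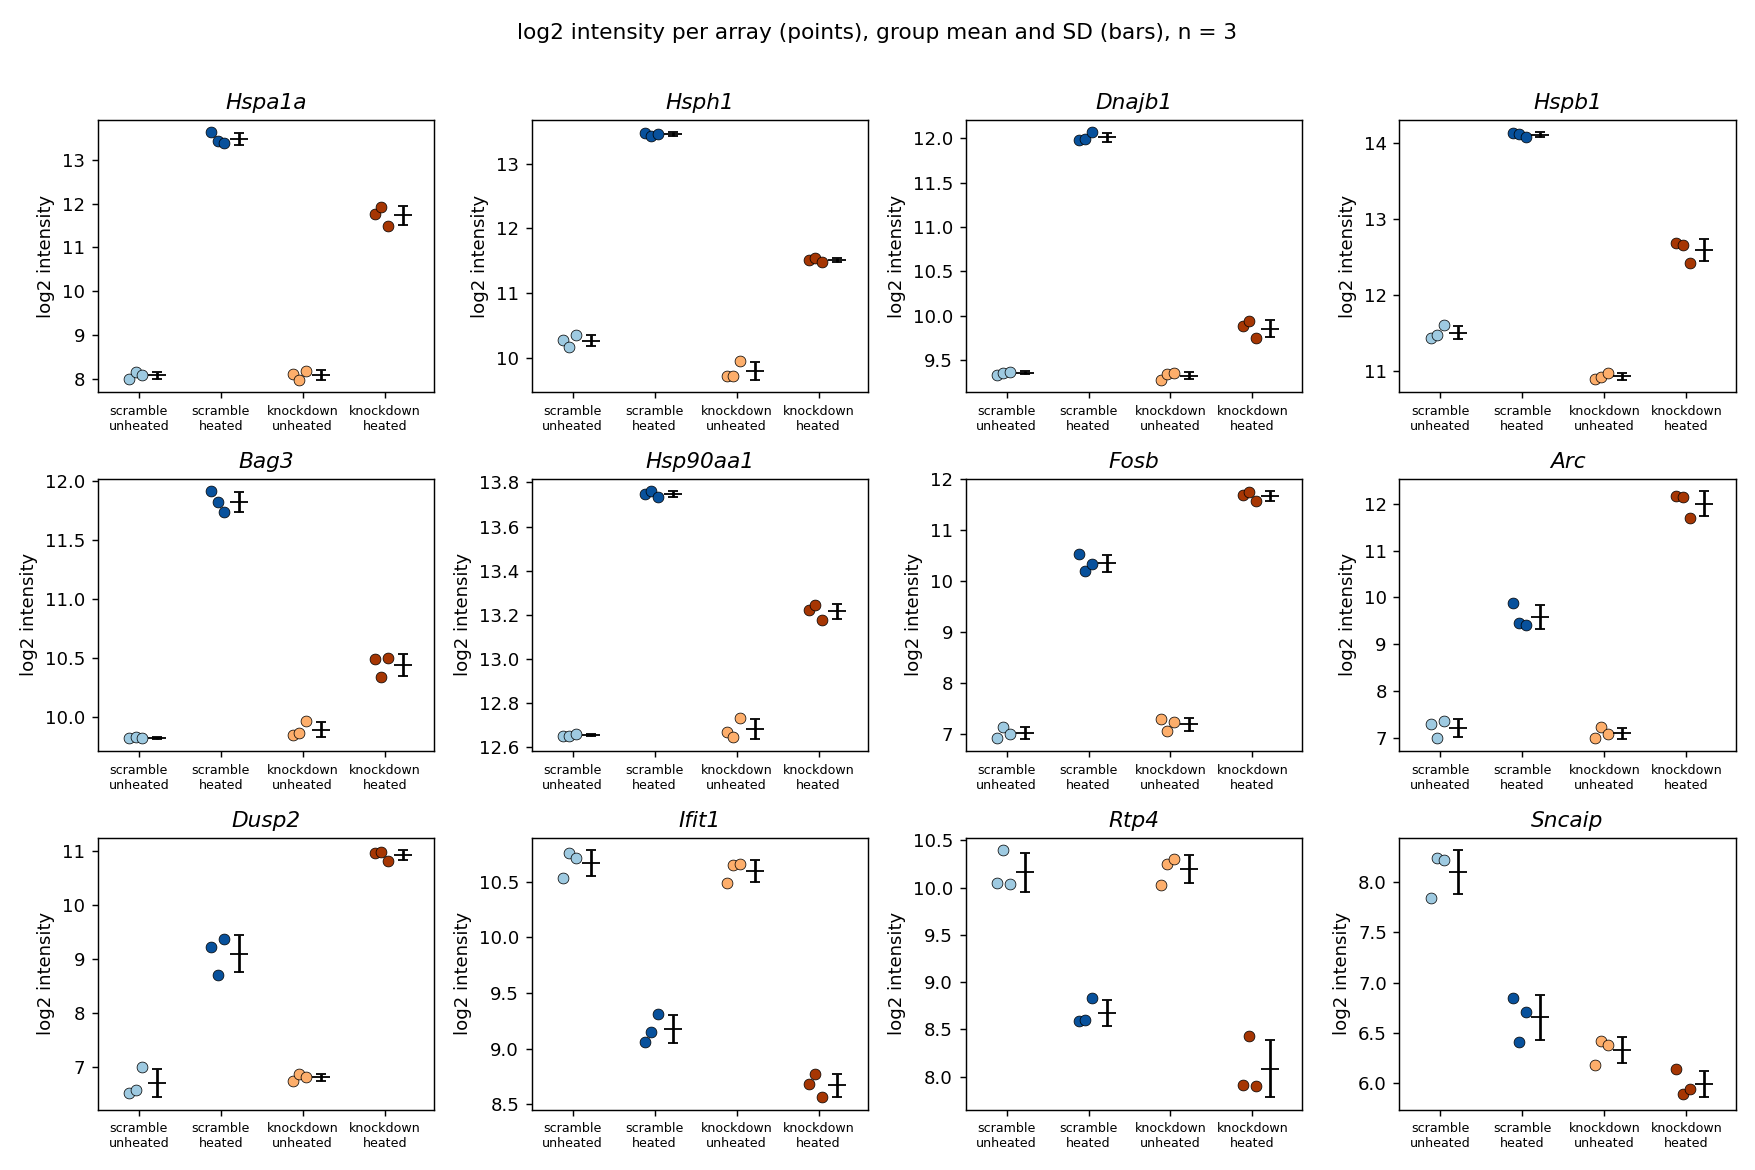
Deposited log2 intensity (vertical axes) of 12 named genes in the 4 groups (horizontal axes); points are single arrays, bars the mean and SD of 3 arrays. Hspa1a rose from a mean of 8.08 to 13.48 with heat in scramble cells and from 8.09 to 11.73 in knockdown cells, while Arc and Dusp2 reached higher levels in heated knockdown cells than in heated scramble cells.

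In unheated cells the comparison of knockdown with scramble asks which genes differ with the HSF1 hairpin without stress. No other hairpin against HSF1 was analysed here, so effects through HSF1 and other effects of the hairpin were not separated in this or any comparison of knockdown cells. The largest falls were in Sncaip, which encodes synphilin-1 (log2 change -1.78 ± 0.14, n = 3 per group, adjusted p = 0.000197, limma), Serpinb9, a granzyme B inhibitor (-1.65 ± 0.10), the phosphatase gene Ctdsp2 (-1.45 ± 0.07, and -1.56 on a second probe set) and Ubn1, a histone chaperone subunit (-1.21 ± 0.08). Next came the placental gene Plac1 (-1.17 ± 0.16), Rmnd5a (-1.03 ± 0.08), the Wnt antagonist gene Sfrp1 (-1.01 ± 0.11), Ccn3 (-0.99 ± 0.08) and Tor1b (-0.99 ± 0.06). Among the 10 largest rises were those of Lncenc1 (1.09 ± 0.12), Pld4 (1.03 ± 0.13), the endothelial lipase gene Lipg (1.00 ± 0.11), Iqcg (0.84 ± 0.10) and the acetylcholine receptor subunit gene Chrnb1 (0.84 ± 0.06).

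Of 29 members of the first chaperone list, 2 were lower and 0 higher in unheated knockdown cells (2 and 2 adjusted over the list alone). Hspb1 was 1.49-fold lower (-0.58 ± 0.07, adjusted p = 0.00247) and Hsph1 1.38-fold lower (-0.47 ± 0.07, adjusted p = 0.00537). The call of Hsph1 was lost when only the 6 arrays compared were fitted (adjusted p = 0.0689). Hspa1a (0.01 ± 0.11), Dnajb1 (-0.03 ± 0.06), Bag3 (0.07 ± 0.06) and Hsp90aa1 (0.03 ± 0.04) did not pass the test, nor did the list (mean -0.03, adjusted p = 0.552).

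Several list shifts in unheated knockdown cells passed the preset test and not the one with an estimated correlation. Of 16 myofibroblast and smooth muscle genes 5 were lower and 0 higher (6 and 0 adjusted over the list alone), and of these the focal adhesion gene Vcl changed most, by -0.59 ± 0.05 (list mean -0.16, adjusted p = 0.000479, and adjusted p = 0.580 with an estimated correlation). Of 22 extracellular matrix and fibroblast genes 4 were lower and 0 higher (8 and 1 adjusted over the list alone), with the collagen gene Col1a2 at -0.48 ± 0.06 (list mean -0.10, adjusted p = 0.00157, and adjusted p = 0.621 with an estimated correlation). Cholesterol synthesis and uptake genes were higher, 4 of 18 with 0 lower (8 and 0 adjusted over the list alone), at a mean of 0.17 (adjusted p = 0.000482, and adjusted p = 0.732 with an estimated correlation). All 14 measured splicing regulators stayed short of the threshold (7 lower and 1 higher adjusted over the list alone) while the list had a mean of -0.08 (adjusted p = 0.0175, and adjusted p = 0.621 with an estimated correlation). This call was also lost without the unheated scramble replicate 1 (mean -0.06, adjusted p = 0.162) and with array weights (mean -0.07, adjusted p = 0.0531).

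The knockdown in unheated cells moved 609 probe sets up and 830 down, 6 and 12 of them by at least 2-fold. Replicates did not overlap for 21.7% of probe sets, against 10% by chance. These counts varied with single arrays. Leaving out unheated knockdown replicates 1, 2 or 3 gave 347, 272 or 244 higher and 440, 477 or 414 lower, and leaving out unheated scramble replicates 2 or 3 gave 309 or 262 higher and 521 or 423 lower. A fit of only the 6 arrays compared gave 166 higher and 351 lower, which is 32.1% higher against 42.3%.

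In heat-shocked cells the comparison of knockdown with scramble asks which genes differ with the HSF1 hairpin under heat. The first chaperone list had the lowest mean change of all lists in this comparison. Dnaja4 was 5.8-fold lower than in heated scramble cells (log2 change -2.54 ± 0.07, n = 3 per group, adjusted p = 8.06e-08, limma), Dnajb1 4.45-fold, Hsph1 3.81-fold, Hspa1a 3.36-fold, Hspb1 2.87-fold, Bag3 2.6-fold and Hsp90aa1 1.45-fold lower. In the first chaperone list 17 of 29 genes were lower and 0 higher (18 and 0 adjusted over the list alone), with a mean of -0.63 (camera adjusted p = 9.51e-11). Of 17 HSP90 and co-chaperone genes 9 were lower and 0 higher (10 and 0 adjusted over the list alone), with Fkbp4 at -0.72 ± 0.06 and Cacybp at -0.60 ± 0.07 (mean -0.27, adjusted p = 7.27e-05). Both lists kept their call with an estimated correlation (adjusted p = 0.00254 and 0.0467). The mitochondrial chaperonin genes Hspe1 and Hspd1 were 1.87-fold and 1.71-fold lower, in a list with 7 lower and 0 higher of 20 (8 and 1 adjusted over the list alone) that had no call (mean -0.11, adjusted p = 0.221). Serpinb9 (-1.95 ± 0.10) and Plac1 (-1.39 ± 0.16) were low here as they were without heat, while Gml, at -1.58 ± 0.12, and the histone gene H2ac4, at -1.39 ± 0.18, were among the 10 largest falls here.

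Immediate-early genes were higher in heated knockdown cells than in heated scramble cells. Of 26 members 18 were higher and 1 lower (20 and 1 adjusted over the list alone), with a mean of 0.63 (camera adjusted p = 1.92e-14, and adjusted p = 0.0442 with an estimated correlation). Dusp2 was 3.54-fold, Ier2 2.98-fold, Fosb 2.49-fold and Jun 2.34-fold higher. The neuronal activity gene Arc, which is not in the list, was 5.36-fold higher and the small GTPase gene Rhob 3.14-fold higher. Targets of ATF4, the transcription factor of the integrated stress response, were also higher, 9 of 21 with 0 lower (12 and 0 adjusted over the list alone), at a mean of 0.39 (adjusted p = 3.06e-07, and adjusted p = 0.626 with an estimated correlation). The glutathione-degrading enzyme gene Chac1 was 2.7-fold and the stress sensor gene Sesn2 1.53-fold higher.

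Other lists differed between heated knockdown and heated scramble cells by smaller means. Cholesterol genes were higher, 10 of 18 with 0 lower (13 and 0 adjusted over the list alone; mean 0.25, adjusted p = 4.90e-05, and adjusted p = 0.658 with an estimated correlation), with Cyp51 and Msmo1 at 0.54 ± 0.11 and 0.53 ± 0.08. Splicing regulators and cold-inducible RNA-binding protein genes were higher, 6 of 14 with 0 lower (8 and 0 adjusted over the list alone; mean 0.18, adjusted p = 0.00133, and adjusted p = 0.413 with an estimated correlation), with Tra2a at 0.49 ± 0.06 and Cirbp at 0.44 ± 0.06. Nucleolar genes were lower, 10 of 24 with 0 higher (14 and 1 adjusted over the list alone), with Polr1b, an RNA polymerase I subunit gene, at -0.49 ± 0.05 (list mean -0.17, adjusted p = 0.000273, and adjusted p = 0.580 with an estimated correlation). In the list of the unfolded protein response of the endoplasmic reticulum 4 of 24 genes were higher and 1 lower (5 and 1 adjusted over the list alone), Herpud1 at 0.81 ± 0.08 and Xbp1 at -0.43 ± 0.06. That list's mean was 0.11 (adjusted p = 0.0220, and adjusted p = 0.626 with an estimated correlation), and its call ended without heated knockdown replicate 3 (mean 0.10, adjusted p = 0.0636).

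In all, 2725 probe sets were higher and 3183 lower in heated knockdown cells than in heated scramble cells, 168 and 166 of them by at least 2-fold. Among the 19938 genes 1628 were higher and 2390 lower past the threshold. Replicates did not overlap for 32.9% of probe sets, against 10% by chance. A common median gave 2070 higher and 3727 lower (35.7% higher against 46.1%), and the count of higher probe sets was 1731 without heated scramble replicate 2. The knockdown effects with and without heat, which share no array, correlated over 19938 genes with r = 0.37, genes not being independent replicates. Of the probe sets called in unheated cells, 300 of 609 higher and 505 of 830 lower ones were called in the same direction in heated cells, where independent lists would share 46.7 and 74.3.

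Heat shock in knockdown cells, the measure of the response that remains, still raised the chaperones. Hspa1a rose 12.5-fold (log2 change 3.64 ± 0.11, n = 3 per group, adjusted p = 2.19e-08, limma), Hsph1 3.28-fold and Hspb1 3.16-fold, while Bag3, Dnajb1 and Hsp90aa1 rose 1.46-fold, 1.45-fold and 1.45-fold. In the first chaperone list 13 of 29 genes were higher and 3 lower (the same adjusted over the list alone), with a mean of 0.39 (camera adjusted p = 0.000273, and adjusted p = 0.0338 with an estimated correlation). The HSP90 list had 4 higher and 5 lower members (the same adjusted over the list alone) and did not pass the test (mean -0.03, adjusted p = 0.934).

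Arc had the largest log2 change with heat in knockdown cells. It rose 29.8-fold (4.90 ± 0.16), Sprr1a 28.7-fold, Fosb 22.3-fold, Dusp2 17.4-fold and Serpinb2 14.5-fold. Krtap4-16 rose from a mean level of 4.96, below the lower quartile of every array, to 9.76, and the cornified envelope gene Lor from 5.60, near that quartile, to 9.43. Of 26 immediate-early genes 25 were higher and 0 lower (also 25 and 0 adjusted over the list alone), with a mean of 1.84 (camera adjusted p = 9.03e-30, and adjusted p = 0.00943 with an estimated correlation). Myofibroblast and smooth muscle genes had a mean of 0.28, with 4 of 16 higher and 0 lower (also 4 and 0 adjusted over the list alone), and the matricellular genes Ccn2 and Ccn1, which respond to growth factors, led them with 1.61 ± 0.10 and 1.41 ± 0.05 (adjusted p = 0.00763, and adjusted p = 0.626 with an estimated correlation).

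Interferon-stimulated genes fell here too, 20 of 26 with 0 higher (21 and 0 adjusted over the list alone; mean -0.70, adjusted p = 5.52e-07, and adjusted p = 0.626 with an estimated correlation). Rtp4, Ifit1 and Ifit3 were 4.32-fold, 3.8-fold and 3.45-fold lower. G2 and mitosis genes were lower, 18 of 24 with 1 higher (the same adjusted over the list alone; mean -0.25, adjusted p = 2.53e-05, and adjusted p = 0.376 with an estimated correlation), Plk1 at -0.54 ± 0.06, while the mitotic gene Cdc20 rose by 0.63 ± 0.06. Outside these lists the histone genes H1f5, H2ac4 and H2bc3 fell by 1.92 ± 0.09, 1.79 ± 0.18 and 1.64 ± 0.12 on the log2 scale. BC023105 fell from a mean level of 6.24 to 3.83, and the zinc finger genes Zfp455 from 7.30 to 5.16 and Zfp975 from 6.78 to 4.69. Their heated levels lay below the lower quartile of every array, so no sizes are given. The circadian list had 7 of 16 genes higher and 1 lower (7 and 2 adjusted over the list alone), with Bhlhe41 at 1.87 ± 0.11 (list mean 0.24, adjusted p = 0.0468, and adjusted p = 0.626 with an estimated correlation). Its call ended with dim probe sets left out (adjusted p = 0.0626), only the arrays compared (0.0732), array weights (0.0533), the replicate block (0.0714) and the mean of all probe sets of a gene (0.0556). It also ended without heated knockdown replicate 1 (mean 0.22, adjusted p = 0.0788), unheated knockdown replicates 1 (0.23, 0.0571) and 3 (0.23, 0.0542), unheated scramble replicates 1, 2 and 3 (0.24 each, with 0.0555, 0.0514 and 0.0606) and heated scramble replicate 3 (0.24, 0.0506).

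In total 5234 probe sets were higher and 5668 lower with heat in knockdown cells, 919 and 261 of them by at least 2-fold. Among the 19938 genes 2638 were higher and 4243 lower past the threshold, so the near balance was not one of genes. Replicates did not overlap for 44.4% of probe sets against 10% by chance. A common median gave 3673 higher and 8545 lower, a share of 30.1% higher against 48%.

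**Figure D2:**
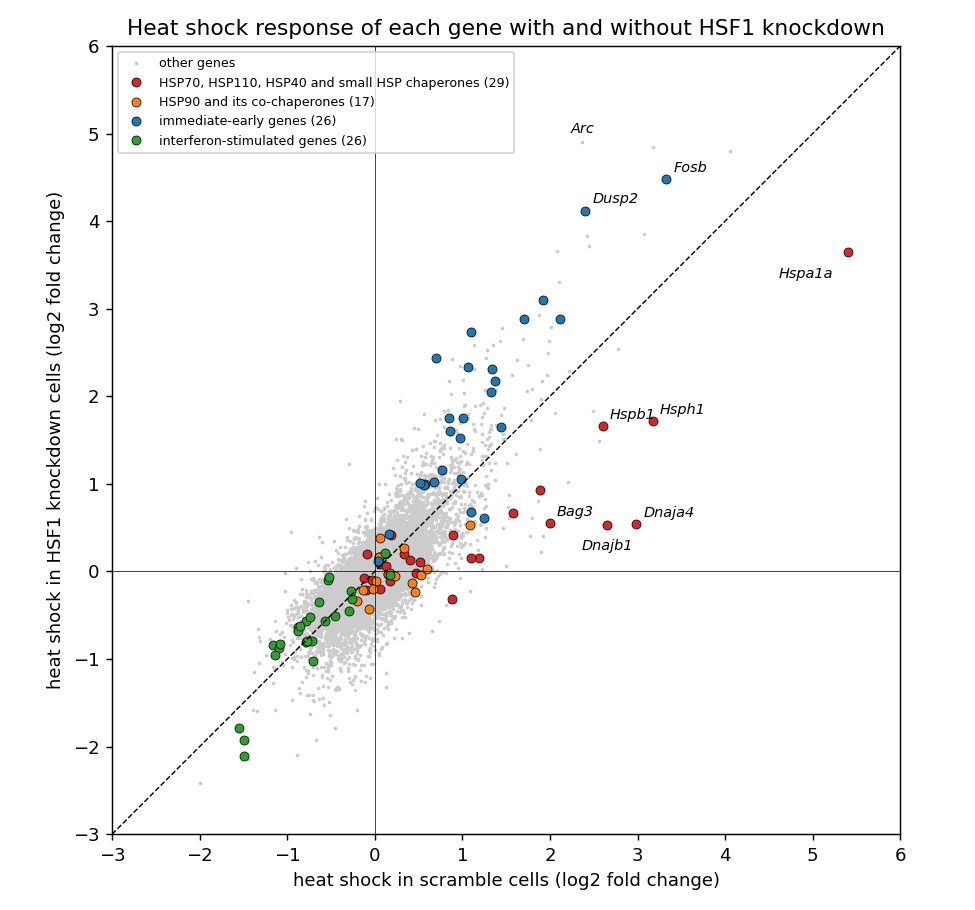
Log2 fold change with heat shock in scramble cells (horizontal axis) against that in HSF1 knockdown cells (vertical axis), 1 point per gene for 19938 genes, with 4 gene lists in colour; the dashed line marks equal changes. Over all genes r was 0.763; most chaperones that rose lie below the line and most immediate-early genes above it.

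The interaction tests directly whether the heat response differed between knockdown and scramble cells. Over 19938 genes the 2 heat responses, which share no array, correlated with r = 0.763 (Spearman's rho 0.671) and a slope of 0.868 of knockdown on scramble values, genes not being independent replicates. The slope was 0.53 over the 46 genes of both cytosolic chaperone lists, 1.33 over immediate-early genes and 1.11 over interferon-stimulated genes. Noise in the scramble values lowers such slopes, so 0.868 does not show a weaker response of genes in general. By count, heat changed 10902 probe sets in knockdown and 8959 in scramble cells.

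Chaperone genes responded less in knockdown cells. The interaction was -2.44 ± 0.10 for Dnaja4 (adjusted p = 3.88e-06, limma, n = 3 per group), -2.12 ± 0.08 for Dnajb1, -1.76 ± 0.16 for Hspa1a, -1.46 ± 0.10 for Hsph1, -1.45 ± 0.09 for Bag3, -0.94 ± 0.10 for Hspb1 and -0.56 ± 0.06 for Hsp90aa1. As a share of the log2 response of scramble cells, knockdown cells kept 67.5% for Hspa1a, 63.8% for Hspb1, 54% for Hsph1, 48.6% for Hsp90aa1, 27.5% for Bag3, 20.1% for Dnajb1 and 18.2% for Dnaja4. Hspb1 and Hsph1 were already lower in unheated knockdown cells (-0.58 and -0.47 on the log2 scale), and this lower starting level is part of their shares. Shares of the linear rise are smaller: Hspa1a rose 42.2-fold in scramble and 12.5-fold in knockdown cells. In the first chaperone list 13 of 29 genes had a negative and 0 a positive interaction (17 and 0 adjusted over the list alone), with a mean of -0.60 (camera adjusted p = 3.11e-13, and adjusted p = 0.00223 with an estimated correlation). In the HSP90 list 6 of 17 were negative and 1 positive (10 and 1 adjusted over the list alone), with Chordc1 at -0.70 ± 0.11 (list mean -0.26, adjusted p = 2.67e-05, and adjusted p = 0.0426 with an estimated correlation). Of 20 mitochondrial chaperone and protease genes 3 were negative and 0 positive (4 and 0 adjusted over the list alone), with Hspd1 at -0.76 ± 0.07 and Hspe1 at -0.59 ± 0.09 (list mean -0.15, adjusted p = 0.00761, and adjusted p = 0.621 with an estimated correlation). Outside the lists the osmolyte transporter gene Slc5a3 (-1.51 ± 0.13), Lpar6 (-1.45 ± 0.13), Tmem171 (-1.43 ± 0.17) and Rpp38 (-1.37 ± 0.09) were among the 10 genes with the largest negative interactions. Gml had mean levels of 5.56, below the lower quartile of every array, without heat and 7.46 with heat in scramble cells, and of 5.66 and 5.88 in knockdown cells, so the size of its difference is not exact.

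Immediate-early genes went the other way, with 14 of 26 positive and 1 negative (21 and 2 adjusted over the list alone), a mean of 0.68 (camera adjusted p = 1.56e-20, and adjusted p = 0.0224 with an estimated correlation). Ier2 responded more in knockdown cells by 1.74 ± 0.12, Dusp2 by 1.72 ± 0.24, Jun by 1.63 ± 0.10 and Zfp36, which encodes an mRNA decay factor, by 1.27 ± 0.14. Outside the list Arc (2.53 ± 0.23), Sprr1a (1.67 ± 0.15), Rhob (1.66 ± 0.14), Snord37 (1.54 ± 0.28) and Dusp8 (1.45 ± 0.08) were among the 10 genes with the largest positive interactions. Snord37 was dim without heat (mean levels 6.84 in scramble and 6.54 in knockdown cells). It lay within 10 kb of a well expressed gene, so its value can include RNA from that neighbour. Of 21 ATF4 targets 6 had a positive and 0 a negative interaction (also 6 and 0 adjusted over the list alone), Chac1 at 1.53 ± 0.11 and Atf3 at 0.78 ± 0.12 (list mean 0.33, adjusted p = 2.49e-06, and adjusted p = 0.626 with an estimated correlation).

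Heat lowered the splicing factor gene Srsf5 and the cold-inducible RNA-binding protein gene Cirbp in scramble cells (-0.81 ± 0.07 and -0.70 ± 0.06). The splicing list as a whole had a positive interaction, with 6 of 14 positive and 0 negative (9 and 0 adjusted over the list alone), Cirbp at 0.63 ± 0.09 and Hnrnpdl at 0.61 ± 0.06 (list mean 0.27, adjusted p = 1.11e-06, and adjusted p = 0.106 with an estimated correlation). Nucleolar genes had a negative one, 6 of 24 with 0 positive (13 and 0 adjusted over the list alone), with Polr1b at -0.48 ± 0.08 and Rrp9 at -0.46 ± 0.07 (list mean -0.21, adjusted p = 6.76e-06, and adjusted p = 0.376 with an estimated correlation). Of 16 myofibroblast and smooth muscle genes 2, Ccn2 (0.68 ± 0.14) and Ccn1 (0.55 ± 0.07), had a positive and 0 a negative interaction (3 and 0 adjusted over the list alone; list mean 0.16, adjusted p = 0.00308, and adjusted p = 0.626 with an estimated correlation). The interferon-stimulated list did not pass the test (mean 0.05, adjusted p = 0.429), and no member passed it, with or without adjusting over the list alone.

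Among the 19938 genes the interaction passed the threshold for 407 with a positive and 935 with a negative value. Over all probe sets it did so for 829 with a positive and 1179 with a negative value, 182 and 73 of them by at least 2-fold. A common median gave 623 and 1595 (28.1% positive against 41.3%), and array weights gave 1483 and 1771. Of 8959 probe sets that changed with heat in scramble cells, 1267 also passed the interaction. Of the probe sets higher with heat in scramble cells, 493 had a negative and 317 a positive interaction, and of the lower ones 220 had a positive and 237 a negative one. Independent lists would share 144, 101, 108 and 153. Of the 493, 103 were called lower with heat in knockdown cells, and of the 220, 29 were called higher, so these reversed. Both tests use the scramble arrays, so part of the excess can come from them. In each of 20 simulations with no interaction 0 probe sets passed both, but such data give almost no interaction calls to share, so this value does not measure that part. Single arrays moved these counts by more than 1.5 times. The interaction counts were 419 and 732 without heated scramble replicate 2, 478 and 736 without unheated scramble replicate 3, 494 and 734 without unheated knockdown replicate 2, and 549 and 750 without unheated knockdown replicate 3. The positive count alone moved that far without unheated knockdown replicate 1 (531), heated scramble replicate 3 (514) and heated knockdown replicate 1 (511). The 1267 became 685, 737, 788 and 831 without the first 4 of these arrays, in that order.

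Of the 30 lists tested, 16 had no call in any contrast. Among them were 6 lists of markers of other cell types, namely epithelial, endothelial, leukocyte, adipocyte, skeletal muscle and neural, whose means lay between -0.14 and 0.26 with a lowest adjusted p of 0.125. The other 10 were the TRiC chaperonin, proteasome, ubiquitin and autophagy, NRF2, metallothionein, p53, G1/S, NF-kB, glycolysis and hypoxia, and heat shock factor lists, with means between -0.14 and 0.28 and a lowest adjusted p of 0.0643.

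**Figure D3:**
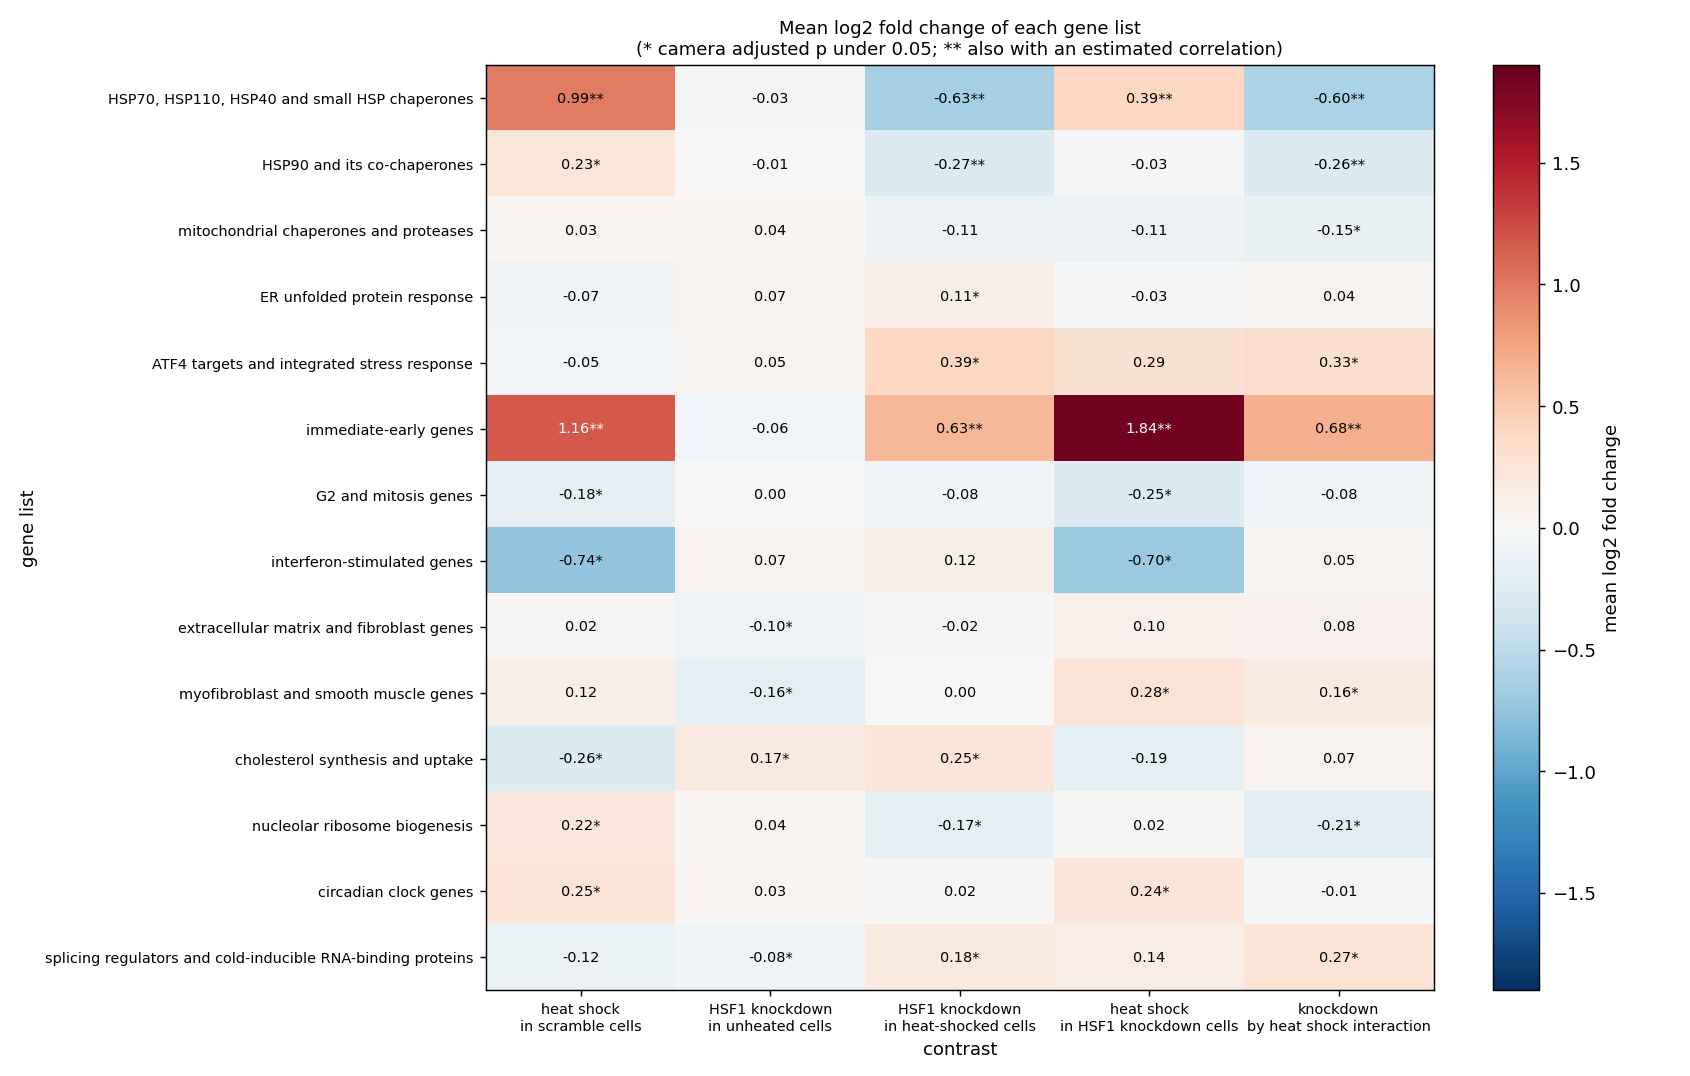
Mean log2 fold change (colour and number) of the 14 gene lists called in at least 1 contrast (rows) in the 5 contrasts (columns); 1 star marks a camera adjusted p under the threshold of 0.05 and 2 stars a call that also held with an estimated correlation. The chaperone lists are positive with heat in scramble cells and negative in the interaction, where immediate-early genes have a mean of 0.68.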

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

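The counts, genes and lists named in the first 2 paragraphs for the interaction differ between scramble and knockdown cells by its own test, the heat response of knockdown cells minus that of scramble cells on the log2 scale. The last paragraph weighs a pattern of heat within each kind of cell. The test of single arrays, the odds ratio adjusted for level and gene density, the count of lower interactions among other heat-induced genes and the 3 genes named for it, the comparison with the list's median, and the sorting of the drawn splits by what they exchange were chosen after the result was seen. The interaction passed the threshold for 829 probe sets with a positive and 1179 with a negative value. In 100 drawn splits that exchanged scramble and knockdown labels within the unheated and within the heated arrays, 2 called as many probe sets, the real one included, a share under 0.05. The highest other split called 5503, several times the real count, which points to a structure of the samples: it exchanged all labels of the heated arrays only, and so tests the sum of both knockdown effects. In 12 drawn splits that kept the heated groups and regrouped the unheated arrays, 994 to 1858 were called, against the real 2008, and in 86 that regrouped the heated arrays, 0 to 2. These splits argue against chance labelling of the arrays as a whole, mainly through those that regrouped the heated arrays. They do not separate a different effect of knockdown with heat from its effect in heated cells alone. For the other contrasts the 6 arrays make only 10 splits, too few for a share under 0.05. In each, 1 split, the real one, called as many probe sets. The real and highest other counts were 8959 and 33 for heat in scramble cells, 1439 and 0 for knockdown in unheated cells, 5908 and 0 for knockdown in heated cells, and 10902 and 1 for heat in knockdown cells.

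Negative interactions were those of Dnaja4 (-2.44), Dnajb1 (-2.12), Hspa1a (-1.76), Gml (-1.68), Slc5a3 (-1.51), Hsph1 (-1.46), Lpar6 (-1.45), Bag3 (-1.45), Tmem171 (-1.43), Rpp38 (-1.37), Hspb1 (-0.94) and Hsp90aa1 (-0.56). The unheated scramble level of Gml, 5.56, lay below the lower quartile of every array, so the size of its value is not exact. Positive ones were those of Arc (2.53), Ier2 (1.74), Dusp2 (1.72), Sprr1a (1.67), Rhob (1.66), Jun (1.63), the taste receptor gene Tas2r143 (1.58), Snord37 (1.54), Chac1 (1.53) and Dusp8 (1.45). The unheated knockdown level of Tas2r143, 5.34, lay below that quartile too, and it lost its call without unheated knockdown replicate 2 (1.53, adjusted p = 0.0537) and without heated scramble replicate 2 (1.41, adjusted p = 0.0502). List means were -0.60 for HSP70, HSP110, HSP40 and small HSP chaperones, -0.26 for HSP90 and its co-chaperones, -0.15 for mitochondrial chaperones and proteases, -0.21 for nucleolar ribosome biogenesis, 0.33 for ATF4 targets, 0.68 for immediate-early genes, 0.16 for myofibroblast and smooth muscle genes and 0.27 for splicing regulators.

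For the larger heat response of immediate-early genes in knockdown cells, a single array as the source is argued against, because the lowest mean interaction of the list without 1 array was 0.65 (without heated scramble replicate 2), 94.7% of the value of 0.68 with all arrays. A larger rise of all heat-induced genes without exception is argued against, because among 182 other genes with an average rise of at least 1, outside the chaperone and immediate-early lists, 11 of 72 calls were lower and 3 of these, Slc5a3, Uspl1 and Rhof, passed a Bonferroni threshold over all probe sets, which needs no independence of genes. Most of these 182 genes did respond more in knockdown cells: 143 (78.6%) had a positive interaction, and 61 of the 72 calls were higher. Whether this wider response accounts for the list's pattern stays open. Their median interaction was 0.34, 50.3% of the list's mean, just past the planned bound of 50%, though 47.1% of its median. The pattern may be part of that wider response. An effect of HSF1 loss also stays open, as does one of the hairpin other than through HSF1, which was not tested.

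More probe sets rose than fell by at least 2-fold with heat, 919 against 261 in knockdown cells and 383 against 75 in scramble cells. These counts do not show such an excess among named genes. Without a fold limit, 2638 named genes were higher and 4243 lower in knockdown cells, and 2798 and 3383 in scramble cells. Both checks below used only genes with a 1-symbol probe set, so the other probe sets in these counts were not examined. A background shift left in the deposited values of the heated arrays is argued against. The 1190 olfactory and vomeronasal receptor genes, which fibroblasts hardly express, had a median log2 change of 0.0039 in knockdown cells and -0.015 in scramble cells. The deposited values were read as normalized, and the median change of all probe sets was also small (0.00027 and 0.00484). A shift of the raw signal, which normalization can remove, was therefore not tested. RNA from an expressed neighbouring gene on either side stays open: among genes dim without heat, in knockdown cells 38 of 91 that rose at least 2-fold (41.8%) lay within 10 kb of a well expressed gene, against 1459 of 8179 (17.8%) that changed by under 0.5, an odds ratio of 3.3 (95% interval 2.11 to 5.13, Fisher's exact test, two-sided, p = 1.23e-07, with genes taken as independent). Adjusted for level and gene density the odds ratio was 2.2 (95% interval 1.4 to 3.44). Best2, Cdo1, Ly6g6c and Snord37 were among the 38, so RNA from neighbours may contribute to rises of dim genes. Strand was not used here, so neighbours upstream and downstream were counted alike, and transcription past the ends of genes was not tested.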

How the results depend on the processing

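No call of a named gene or list reversed. The larger of the higher and lower counts did change sides, without unheated scramble replicate 1 for heat in scramble cells (3951 higher, 3733 lower) and with at least a 2-fold change for all contrasts but knockdown in unheated cells. Of 497 calls of named genes, 382 kept their direction and call under every alternative that tested them and 115 lost the call under at least 1 of the 23. Of 34 list calls, 30 held under every alternative that tested them except the estimated correlation, which kept 10. Lists were not tested with the 2-fold threshold or with 1 probe set per named gene only. With only the arrays compared they were not tested for the interaction. With the estimated correlation, the HSP90 list with heat in scramble cells (0.23) lost its call (adjusted p = 0.146). Where a count moved, the cause was not tested except for the 2-fold threshold, which by construction only removes calls. Knockdown in unheated cells had 962 higher with dim probe sets left out, 949 with trend and robust options, 1000 with array weights, and 166 higher and 351 lower with only the arrays compared, a fit with fewer samples. Knockdown in heated cells had 1740 higher with only the arrays compared. Heat in knockdown cells had 2837 higher and 4526 lower with 1 probe set per gene, which is 38.5% higher against 48%. That set has fewer probe sets, but the higher calls fell by more than the lower ones. The same contrast had 8545 lower with a common median, which shifted its median by -0.097. Array weights gave 1483 and 1771 for the interaction and 2065 for its overlap with heat. With at least a 2-fold change the higher and lower counts were 383 and 75, 6 and 12, 168 and 166, 919 and 261, and 182 and 73, in the order of the contrasts. Leaving out 1 array gave 244 to 568 higher and 414 to 803 lower for knockdown in unheated cells, 1731 to 2777 higher for knockdown in heated cells, 419 to 861 and 732 to 1169 for the interaction, and 685 to 1083 for its overlap with heat. The other counts stayed within 1.5 times.

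The replicate numbers were also used as a block. They do not pair the samples: 2 of 18 same-number pairs had deviations correlated over 0.1 (r from -0.14 to 0.27), and 4 of 12 arrays were closest to an array of their own number. The block gave 4155 and 4447 with heat in scramble cells, 443 and 668 for knockdown in unheated cells, 2514 and 3000 for knockdown in heated cells, 5038 and 5510 with heat in knockdown cells, 649 and 940 for the interaction, and 1010 for its overlap with heat. Of the list calls, that of the circadian list with heat in knockdown cells ended with the block (0.24, adjusted p = 0.0714). The alternatives planned for the Hsf1 level were not run, as that level was not analysed here. Without detection calls, signal over background limits what dim probe sets can show.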

Other observations

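The gene classes in this part were chosen after the leading genes were seen, from symbols alone, so their tests describe the same data they came from. Replication-dependent histone genes, which are transcribed in S phase, were lower in heated knockdown than in heated scramble cells, 21 of 27 with 0 higher, at a mean log2 change of -0.69 (camera adjusted p = 5.51e-15 over 40 tests of 8 classes, and adjusted p = 0.0601 with an estimated correlation). In unheated knockdown cells their mean was already -0.14, with 0 of 27 past the threshold in limma (adjusted p of the class 0.000418, and adjusted p = 0.361 with an estimated correlation). Their heat response was -0.24 in scramble and -0.79 in knockdown cells, and the interaction had a mean of -0.55 with 14 lower and 0 higher (adjusted p = 3.01e-12, and adjusted p = 0.0822 with an estimated correlation). Zinc finger genes with a Zfp symbol were lower with heat in knockdown cells for 197 of 347 and higher for 32 (mean -0.33). The interaction of this class was -0.20, with 68 lower and 7 higher (adjusted p = 6.04e-09, and adjusted p = 0.0392 with an estimated correlation).

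Feedback inhibitors of growth factor signalling of the Sprouty and Spred class responded more in knockdown cells, 4 of 7 with 0 less (interaction mean 0.55, adjusted p = 9.20e-06, and adjusted p = 0.0247 with an estimated correlation). Their mean change with heat was 0.03 in scramble and 0.58 in knockdown cells. The class was already lower in unheated knockdown cells, 3 of 7 with 1 higher (mean -0.23, adjusted p = 0.00473, and adjusted p = 0.0805 with an estimated correlation), and this lower starting level is part of the interaction. The H/ACA box small nucleolar RNA genes rose with heat in knockdown cells, 14 of 20 with 1 lower (mean 0.57, adjusted p = 1.06e-06, and adjusted p = 0.234 with an estimated correlation). The guanylate-binding and IRG GTPase genes, which interferon induces, were lower with heat in scramble cells, 8 of 10 with 0 higher (mean -0.66, adjusted p = 8.57e-05, and adjusted p = 0.234 with an estimated correlation). Their interaction did not pass the test (mean 0.16, adjusted p = 0.0941).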
